A study of Mus musculus with 6 samples.

How the data were processed

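The samples were hearts of C57BL/6 mice aged 6 to 8 weeks, 3 control and 3 given Ang II, with 1 RNA-seq library per heart. Per the labels, mRNA was taken with poly-T beads from 10 µg of total RNA with an RNA integrity number above 7, and paired-end libraries had inserts of 300 ± 50 bp. The dose and duration of Ang II and the strandedness of the libraries are not given in the labels. Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 are named per the submitters' processing notes, without their roles. The notes name the mouse build mm8, but of 55141 gene IDs shared with GENCODE M21, 51957 (94.2%) had its GRCm38 coordinates, and positions are given on that build.

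The deposited table holds FPKM and an estimated count for each of 55401 Ensembl genes and 6 libraries, with gene ontology and KEGG terms. The authors' FPKM values were used as deposited, with 0.0001 standing for 0. The authors' estimated count values are whole numbers, and all 11 low values that could be checked against FPKM had been rounded up. The design fixed before the data were examined assumed FPKM alone, with limma as the gene test, and named edgeR's test on counts in its place should the table hold raw ones. The table holds estimated counts, so that condition was not strictly met. Making edgeR the main gene test was a choice made after the table was seen. Rounded estimates are not raw counts, and fitted dispersions treat them as if they were.

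Counts were tested with edgeR 4.0.16 (quasi-likelihood, trimmed mean of M-values scaling, filterByExpr, two-sided) in R 4.3.3, leaving 16759 genes, with a Benjamini-Hochberg adjusted p under 0.05 as threshold. Standard errors were derived from edgeR's log2 change and its test statistic. CPM used the scaled library sizes. Gene lists, 33 in number and fixed before the data were examined, were tested with camera in limma 3.58.1 on log2(FPKM + 0.5) for the 12095 genes with FPKM of at least 0.5 in 3 libraries, with a preset inter-gene correlation of 0.01. Lists needed 3 such members, which left 32, since lymphocyte markers had too few. For some lists camera therefore covered fewer members than the tests on counts. Of 762 list genes fixed, 760 were found, and 24 stand in more than 1 list. Camera asks whether a list ranks higher or lower than the other genes; fry, which was also run, tests whether a list's genes move one way on balance and does not compare it with other genes. Terms with 10 to 500 tested members were tested with a one-sided Fisher's exact test against tested genes with any term. DESeq2 1.42.0 and limma on FPKM were run beside edgeR. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

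Genes are named by a rule fixed in advance. It takes up to 6 genes with the largest change per direction among those past the threshold, with groups that do not overlap and a mean FPKM of at least 2 in a group, predicted genes left out. It adds the 3 members with the smallest p of the PPARα, NF-κB target, hypertrophy and matrix lists; the 2 with the smallest p of each other list that passed; and 12 genes set in advance. It named 46 genes. Applying its first part without Ang II replicate 1 was chosen after the data were seen, and other genes outside the rule are chosen after their values were seen.

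Alternatives covered scaling, filters, pseudocounts, weights per library, the replicate number as a block, a transcript length correction and each library left out in turn. Libraries held 51202916 to 63564869 counts. The chi-square per degree of freedom between libraries of a group ran from 34.5 to 495, where counting error alone gives about 1. Tested on simulated data with the spread of all 6 libraries, edgeR called 0 of 335 genes changed 1.5-fold, 2 of 335 changed 2-fold and 132 of 330 changed 4-fold, and 15 of 80052 unchanged genes. With the spread of the libraries left without Ang II replicate 1, it called 1 of 335, 35 of 335 and 209 of 330. It also called 24 of 81647 unchanged genes. The 15 false calls stood beside 2 and 132 changed genes called, and the 24 beside 1, 35 and 209. In both settings false calls thus made up a larger share of all calls than the adjusted p threshold allows. Camera called 60 of 60 lists moved by 0.5 on the log2 scale and 0 of 660 unmoved lists in simulations with independent genes, which do not show how it behaves when genes are correlated. No sample was left out of the comparison, and corynoline-treated animals were not analysed here. The result for 1 gene called without Ang II replicate 1 is not reported here.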

Results

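Poly(A) RNA from the hearts of C57BL/6 mice was sequenced in 2 groups, 3 control mice and 3 mice given angiotensin II (Ang II). This peptide hormone constricts vessels, raises blood pressure and is used in mice to produce cardiac hypertrophy. The mice were 6 to 8 weeks old, and the 6 hearts came from separate animals. Estimated counts summed to 57504794, 57844780 and 53583726 in control replicates 1, 2 and 3 and to 51202916, 63564869 and 62954020 in Ang II replicates 1, 2 and 3. Mitochondrially encoded genes took 35.8% to 47.6% of them. Another 11.9% to 17.2% fell on 4 nuclear pseudogenes of mitochondrial sequence, and reads can be split between such copies. The series title concerns corynoline, PPARα and NF-κB; no library from a corynoline-treated animal was analysed here, so the comparison asks how Ang II alone changed the heart's transcripts, PPARα and NF-κB genes included.

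Hbegf, Xirp1, Ccn2 and P2rx5 transcripts rose in Ang II hearts. The growth factor Hbegf, a ligand of the epidermal growth factor receptor, was 7.42-fold higher. Xirp1, an actin-binding protein of the intercalated disc, was 4.62-fold higher, Ccn2 (connective tissue growth factor) 3.77-fold and P2rx5, an ATP-gated ion channel, 3.54-fold. Red blood cell, antigen presentation, interferon-induced, endothelial and immediate early genes ranked lower than other genes as lists by camera with a preset correlation, and none of these calls held with an estimated correlation (adjusted p from 0.363 to 0.706). The PPARα and NF-κB target lists did not pass camera with all 6 libraries, though the PPARα list passed in 3 of its alternatives with them. Ang II replicate 1 lay apart from the other 5 libraries, and 6 genes passed with it and 129 without it.

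Hbegf (ENSMUSG00000024486; GRCm38 chromosome 18, 36504927 to 36515805, minus strand) rose from 5.75 ± 0.571 to 42.7 ± 11.0 CPM (normalised read counts on edgeR's CPM scale; mean ± SD, n = 3). Its log2 change was 2.89 (SE 0.24), with an adjusted p of 0.0398 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ccn2 (ENSMUSG00000019997; chromosome 10, 24595442 to 24598683, plus strand) rose from 46.9 ± 2.90 to 177 ± 11.6 CPM (log2 change 1.91, SE 0.14, adjusted p = 0.0398 by edgeR). Xirp1 (ENSMUSG00000079243; chromosome 9, 120013755 to 120023598, minus strand) rose from 102 ± 13.3 to 471 ± 84.6 CPM (log2 change 2.21, SE 0.21). P2rx5 (ENSMUSG00000005950; chromosome 11, 73160421 to 73172685, plus strand) rose from 11.2 ± 1.78 to 39.5 ± 2.43 CPM (log2 change 1.83, SE 0.17). Both had an adjusted p of 0.0484 in edgeR's test. The list of genes past the threshold also held Fam13a (log2 change 1.80, SE 0.15) and the predicted gene Gm45774 (2.23, SE 0.17). Both fell outside the rule for named genes and were chosen after their values were seen. Gm45774 lies antisense to the metallothionein gene Mt2 and overlaps it, so its counts are uncertain. Ccn2 overlaps the antisense gene Gm15270, and Xirp1 lies within the span of Cx3cr1 on the same strand. In all, 6 of 16759 genes tested rose and 0 fell, and at an unadjusted p under 0.05 edgeR gave 598 higher and 660 lower. DESeq2 called 276 genes on the same counts, 159 higher and 117 lower, including the 6. Limma on FPKM, the gene test fixed in advance for a table without raw counts, called 3 genes and none of the 6. It gave 556 of 12095 genes tested at an unadjusted p under 0.05. Without Ang II replicate 1, edgeR called 129 genes, 93 higher and 36 lower, again with all 6. By edgeR 0 genes passed without control replicate 1, 2 or 3 or Ang II replicate 3. At an unadjusted p under 0.05 stood 893 of 17599, 987 of 17434, 851 of 17493 and 1114 of 17400 genes tested. With no change at all, a share of about 0.05 would do so. Without Ang II replicate 2 there were 2 calls, both lower and neither among the 6.

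**Figure D1:**
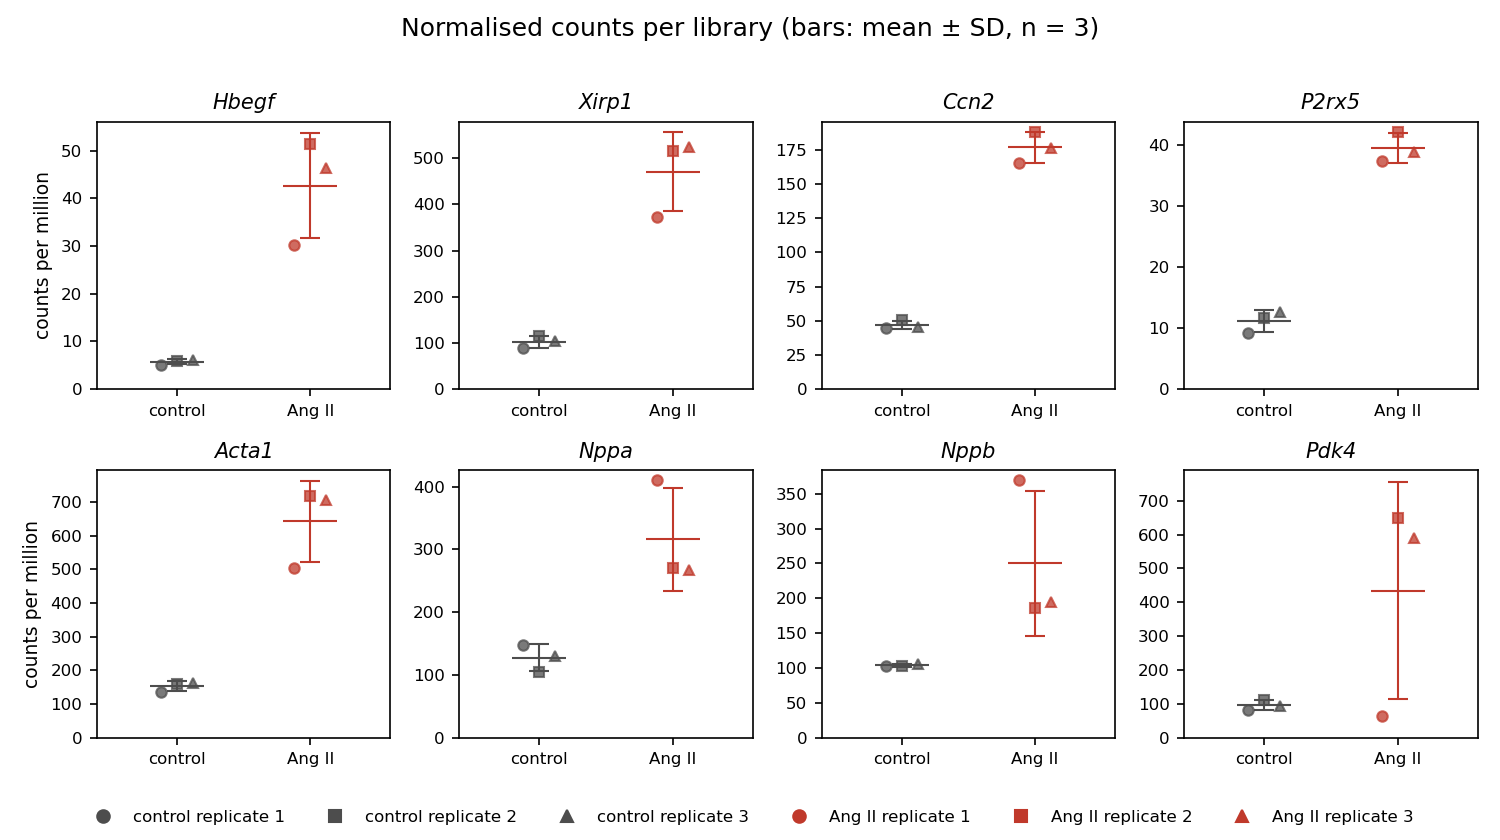
CPM of 8 genes in each library (y axes, linear from 0), by group (x axis); points are the 3 mice per group and bars the mean ± SD. Hbegf, Xirp1, Ccn2 and P2rx5 passed the test over all genes, and Pdk4 stood at 64.8 CPM in Ang II replicate 1 against 650 and 589 CPM in replicates 2 and 3.

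Fetal and hypertrophy-associated cardiomyocyte genes ranked higher as a list by camera with the preset correlation (adjusted p = 5.72e-13; adjusted p = 0.363 with an estimated correlation), and did not pass fry (adjusted p = 0.182). Of 21 tested members, 19 had a fold change above 0, with a median log2 change of 0.89; in edgeR's test 1 passed over all genes tested (Xirp1), 12 were higher and 0 lower at an unadjusted p under 0.05, and 9 passed adjusted over the list alone, all higher. DESeq2 called 8 higher and 0 lower. The skeletal α-actin gene Acta1, a marker of the fetal programme, stood at 153 ± 15.1 CPM in control and 643 ± 120 CPM in Ang II hearts (log2 change 2.07, SE 0.20). It fell just short of the threshold over all genes, at an edgeR adjusted p of 0.0517. The natriuretic peptide genes were among the 9: Nppa stood at 127 ± 21.6 and 316 ± 82.2 CPM and Nppb at 103 ± 1.62 and 250 ± 104 CPM, log2 changes of 1.31 (SE 0.24) and 1.27 (SE 0.29). Xirp2, a relative of Xirp1, stood at 161 ± 23.9 and 408 ± 40.4 CPM. Myh7, the β-myosin heavy chain often used as a hypertrophy marker, gave 772 ± 76.2 CPM in control and 710 ± 69.7 CPM in Ang II hearts (log2 change -0.12, SE 0.17; edgeR adjusted p = 0.877). Sarcomere, calcium handling and energy genes of cardiomyocytes, with 24 of 26 folds above 0 and a median of 0.28, passed camera as well (adjusted p = 0.0033; adjusted p = 0.808 with an estimated correlation). Here edgeR and DESeq2 called 0 members, 0 passed adjusted over the list alone and 2 were higher at an unadjusted p under 0.05, Ttn and Mb. The camera call was lost with quantile normalization (adjusted p = 0.386) and without Ang II replicate 2 (0.0772).

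Extracellular matrix genes had 30 of 44 tested folds above 0 and 14 below, with a median log2 change of 0.17. Ccn2 passed over all genes tested in edgeR's test, 10 were higher and 2 lower at an unadjusted p under 0.05, DESeq2 called 5 higher and 0 lower, and 3 of 44 members passed adjusted over the list alone, all higher. These were Ccn2, the latent TGF-β binding protein gene Ltbp2 (1.81 ± 0.0495 against 4.04 ± 0.518 CPM) and the collagen-binding Fmod, at under 2 CPM in every library. The main fibrillar collagen gene Col1a1 stood at 46.3 ± 4.56 CPM in control and 35.1 ± 1.61 CPM in Ang II hearts (log2 change -0.40, SE 0.14; edgeR adjusted p = 0.583). Postn, a marker of activated fibroblasts, stood at 31.3 and 30.0 CPM in Ang II replicates 2 and 3 and at 7.27 CPM in replicate 1, against 19.6 ± 1.00 CPM in control hearts (log2 change 0.22, SE 0.49). On 38 members the list did not pass camera (adjusted p = 0.18, and adjusted p = 0.871 with an estimated correlation). It passed, higher, with no filter (0.0184), on log2 CPM (0.0191) and with a transcript length correction (0.0443).

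PPARα, its partners and its targets in fatty acid uptake and oxidation did not pass as a list with all 6 libraries (camera adjusted p = 0.153, Up; adjusted p = 0.871 with an estimated correlation). Of 40 tested members, 32 had a fold change above 0, with a median log2 change of 0.14. With the same 6 libraries it passed, higher, with arrayWeights (3.92e-05), on log2 CPM (0.0132) and with a transcript length correction (0.0443), and its direction was Down with quantile normalization (0.795). In edgeR's test 0 passed over all genes, 3 reached an unadjusted p under 0.05 and 1 passed adjusted over the list alone, and DESeq2 called 2 higher. The member that passed was Angptl4, an inhibitor of lipoprotein lipase (3.11 ± 0.743 against 11.3 ± 4.18 CPM, log2 change 1.87, SE 0.32). Both Angptl4 and Pdk4 also stand in the list of glucocorticoid-induced genes. Pdk4, the kinase that switches off pyruvate dehydrogenase and is induced by both PPARα and glucocorticoids, stood at 650 and 589 CPM in Ang II replicates 2 and 3 but 64.8 CPM in replicate 1, against 95.2 ± 15.3 CPM in control hearts. Cpt2, a carnitine palmitoyltransferase of the inner mitochondrial membrane, stood at 92.6 ± 1.51 and 121 ± 5.74 CPM (log2 change 0.39, SE 0.13). Ppara itself was low, at 2.83 ± 0.675 and 2.08 ± 1.07 CPM (log2 change -0.44, SE 0.45; edgeR adjusted p = 0.836). Without Ang II replicate 1 the list passed camera (adjusted p = 8.97e-08, Up; adjusted p = 0.775 with an estimated correlation), 1 member passed over all genes, Pdk4, and 15 passed adjusted over the list alone, all higher.

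NF-κB target genes did not pass as a list (camera adjusted p = 0.358, Down; adjusted p = 0.871 with an estimated correlation; 0.137 without Ang II replicate 1). Camera covered 23 members. Of 36 members tested on counts, 16 had folds above 0 and 20 below. By edgeR 0 were called over all genes and 3 reached an unadjusted p under 0.05, all lower. Adjusted over the list alone 1 passed, and DESeq2 called 1. That gene was Nos2, the inducible nitric oxide synthase, at 12.5 ± 0.302 CPM in control and 5.94 ± 0.575 CPM in Ang II hearts (log2 change -1.07, SE 0.15; edgeR adjusted p = 0.139 over all genes). The inhibitor Tnfaip3 gave a log2 change of -0.76 (SE 0.25) and the chemokine Cxcl10, under 1 CPM in every library, -1.29 (SE 0.47). Receptors, kinases and subunits of the pathway had 0 of 28 members called by edgeR or DESeq2, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.339). The subunit gene Rela stood at 4.97 CPM in Ang II replicate 1 and at 17.1 and 18.5 CPM in replicates 2 and 3, against 21.2 ± 3.41 CPM in control hearts, and Nfkb1 gave a log2 change of -0.19 (SE 0.21). Il6 had 0, 14 and 0 counts in control and 4, 0 and 0 counts in Ang II libraries and was not tested, Il1b lay between 21 and 130 counts and Tnf between 0 and 37. Agtr1a, the main receptor of Ang II, stood at 16.6 ± 0.660 and 13.5 ± 1.95 CPM (log2 change -0.30, SE 0.16; edgeR adjusted p = 0.715).

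Antigen presentation, interferon-induced, endothelial and granulocyte lists ranked lower in Ang II hearts by camera with the preset correlation, and none of the 4 held with an estimated correlation (adjusted p from 0.363 to 0.706). Antigen presentation genes had all 15 tested folds below 0, with a median log2 change of -0.35. Of these, edgeR called 0 over all genes, 5 reached an unadjusted p under 0.05, and DESeq2 called 2. The class II gene H2-Eb1 was the 1 that passed adjusted over the list alone (33.3 ± 1.72 against 20.1 ± 2.12 CPM). Ciita, the activator of class II genes, stood at 1.44 ± 0.237 against 0.517 ± 0.212 CPM. Camera gave an adjusted p of 5.59e-06, and adjusted p = 0.363 with an estimated correlation. Interferon-induced genes had 25 of 30 folds below 0 (median -0.24; camera adjusted p = 1.13e-06; adjusted p = 0.363 with an estimated correlation). By edgeR 0 were called over all genes and 7 were lower at an unadjusted p under 0.05, and DESeq2 called 2. Adjusted over the list alone 2 were lower, the guanylate-binding proteins Gbp3 (18.8 ± 1.23 against 11.8 ± 1.16 CPM) and Gbp7. The interferon list's median in Ang II replicate 1 was 0.11 above the control mean, against -0.55 and -0.52 in replicates 2 and 3. Endothelial markers had 13 of 20 folds below 0 (median -0.27; camera adjusted p = 0.00462; adjusted p = 0.706 with an estimated correlation). In edgeR's test 0 passed over all genes and 5 reached an unadjusted p under 0.05, and DESeq2 called 2. Adjusted over the list alone 2 passed, the VEGF receptor gene Kdr (138 ± 19.7 against 80.5 ± 4.79 CPM) and Vwf (53.8 ± 3.20 against 35.7 ± 3.33 CPM). Neutrophil and mast cell markers passed camera (adjusted p = 0.00301; adjusted p = 0.363 with an estimated correlation) on 4 members, though not with median-of-ratios scaling (0.0631), quantile normalization (0.0635), no filter (0.152), arrayWeights (0.132) or log2 CPM (0.0942). Of 10 members tested on counts, 0 were called by edgeR or DESeq2, with 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. S100a8 and S100a9 were its leading genes, at 1.45 ± 0.708 against 0.535 ± 0.0659 CPM and 4.27 ± 3.51 against 1.49 ± 0.630 CPM.

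Red blood cell and platelet genes had the lowest list median. Of 12 tested members, 11 had folds below 0, with a median log2 change of -1.83. Over all genes 0 passed in edgeR's test, 8 reached an unadjusted p under 0.05, DESeq2 called 6, and 8 passed adjusted over the list alone, all lower. Alas2, the erythroid enzyme that starts haem synthesis, stood at 14.7 ± 6.74 CPM in control and 3.40 ± 0.281 CPM in Ang II hearts, and the globin gene Hba-a2 at 336 ± 149 and 111 ± 3.34 CPM. Reads of the near-identical globin genes can be split between copies. The 4 globin genes together took 0.160%, 0.0914% and 0.137% of counts in control and 0.0501%, 0.0487% and 0.0517% in Ang II libraries. On 7 members camera gave an adjusted p of 7.21e-14, and adjusted p = 0.363 with an estimated correlation.

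Immediate early and heat shock genes had 18 of 26 folds below 0, with a median log2 change of -0.56 (camera adjusted p = 1.07e-05; adjusted p = 0.706 with an estimated correlation). In edgeR's test 0 passed over all genes, 1 reached an unadjusted p under 0.05 higher and 9 lower, and adjusted over the list alone 1 was higher and 5 were lower; DESeq2 called 1 higher and 6 lower. Dusp1, a phosphatase of MAP kinases, stood at 65.7 ± 5.80 and 37.0 ± 1.3 CPM, whereas the stress-induced transcription factor Atf3 stood at 11.1 ± 7.98 and 110 ± 40.9 CPM (log2 change 3.31, SE 0.69). In the same list control replicate 1 had a median of -0.45, near the -0.55 to -0.64 of the Ang II libraries. Glucocorticoid-induced genes ranked higher (camera adjusted p = 0.00101; adjusted p = 0.706 with an estimated correlation). Over all genes edgeR called 0 of 14 members, with 7 higher and 2 lower at an unadjusted p under 0.05, 5 called by DESeq2 and 1 by limma, and 7 higher and 1 lower adjusted over the list alone. The metallothionein genes Mt2 (6.29 ± 2.40 against 44.7 ± 2.25 CPM; log2 change 2.83, SE 0.29; edgeR adjusted p = 0.0517) and Mt1 (63.3 ± 11.7 against 154 ± 16.4 CPM) led it. They also led the oxidative stress list, which holds them too, and 7 of the 14 members stand in other lists. Without these 7 the glucocorticoid list did not pass camera with all 6 libraries (adjusted p = 0.744). The glucocorticoid list's median was -0.09 in Ang II replicate 1 and 0.80 and 0.67 in replicates 2 and 3. Oxidative stress genes passed camera (adjusted p = 0.0218; adjusted p = 0.706 with an estimated correlation). Over all genes 0 were called by edgeR, with 4 higher and 1 lower at an unadjusted p under 0.05, 3 called by DESeq2, 1 by limma and 4 higher adjusted over the list alone. Without Ang II replicate 1 that list no longer passed (adjusted p = 0.0925), nor without control replicate 3 (0.0684), with the replicate number as a block (0.0957), with arrayWeights (0.132), with the length correction (0.0776) or with quantile normalization (0.273).

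Nuclear-encoded subunits of the respiratory chain had 45 of 48 folds above 0 (median 0.31; camera adjusted p = 2.01e-06; adjusted p = 0.706 with an estimated correlation). Of them 0 were called by edgeR or DESeq2, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05, Uqcrb. Its values were 636 CPM in Ang II replicate 1, 393 and 394 CPM in replicates 2 and 3, and 326 ± 7.44 CPM in control hearts. Ndufa9 stood at 303 ± 8.96 and 364 ± 22.1 CPM, a difference that changed sign with quantile normalization. The list's median was 0.72 in replicate 1, where short transcripts and ribosomal protein genes were also higher, and 0.07 and 0.11 in the other 2. Once the length trend was removed, the median was 0.33 in replicate 1, 0.08 and 0.11 in the other 2, and at most 0.014 in controls. With quantile normalization the list did not pass (camera adjusted p = 0.794). Mitochondrially encoded genes had 12 of 13 folds below 0 (median -0.25; camera adjusted p = 0.00545; adjusted p = 0.706 with an estimated correlation). No member, 0 of 13, was called by edgeR or DESeq2, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. The call was lost without control replicate 1 (adjusted p = 0.709), Ang II replicate 2 (0.0548) or Ang II replicate 3 (0.0949), with no filter (0.170), median-of-ratios scaling (0.119), quantile normalization (0.386) and log2 CPM (0.135). In control replicate 1, mt-Co1 stood at 195850 CPM against 112720 and 136814 CPM in the other 2 controls. Its fellow member mt-Nd4l stood at 2999 ± 955 CPM in control and 2016 ± 666 CPM in Ang II hearts. Counts of mitochondrially encoded genes are uncertain, since reads can be split with their nuclear pseudogenes.

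**Figure D2:**
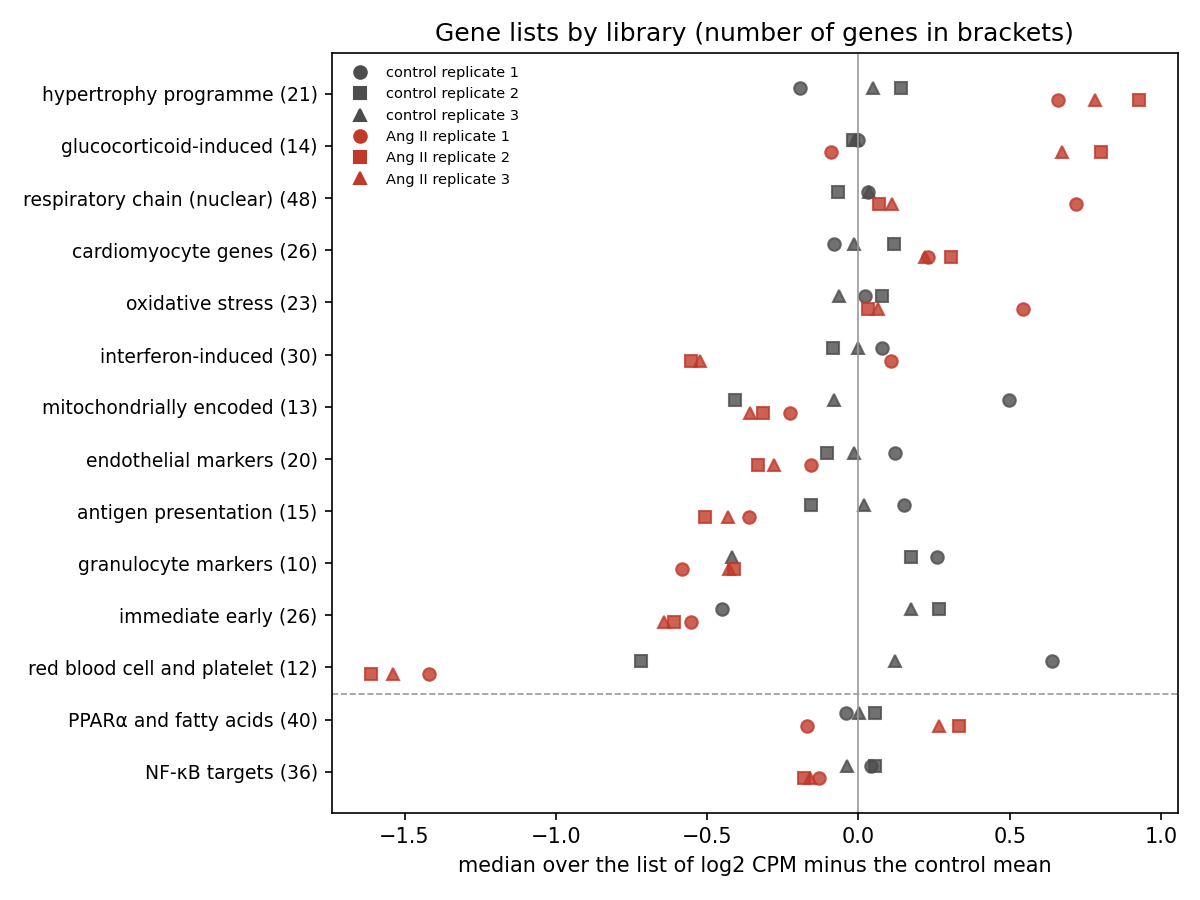
Median over each list's genes of log2 CPM minus the control mean (x axis), 1 point per library, for the 12 lists that passed camera and, under the dashed line, the PPARα and NF-κB target lists. Brackets give the genes per list tested on counts, and camera covered fewer genes in some lists. Red blood cell genes lay between -1.42 and -1.61 in the 3 Ang II libraries and between -0.72 and 0.64 in the controls, and the nuclear respiratory chain list was at 0.72 in Ang II replicate 1 alone.

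Of the 32 lists tested, 12 passed camera with the preset correlation, 5 higher and 7 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.363) and 0 by fry (smallest adjusted p = 0.0797), which asks whether a list's genes move one way on balance. Without Ang II replicate 1 there were 14, 6 higher and 8 lower, of which 11 were the same lists in the same direction, again with 0 by an estimated correlation (smallest adjusted p = 0.368) or by fry (0.076). The 20 lists that did not pass had adjusted p-values from 0.0968, for clock genes, to 0.814. Without Ang II replicate 2, endothelial markers (0.0796) and cardiomyocyte genes (0.0772) did not pass either.

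Ang II replicate 1 had a mean Pearson's r across genes of 0.926 with the other libraries, against 0.959 to 0.963 for the other 5. The first principal component, 52.1% of the variance, placed it at -63.5, against -11.7 to 23.7. Ribosomal protein genes took 2.82% of its counts and 1.17% to 1.32% elsewhere, and the nuclear RNA Malat1 had 1985 counts against 11222 to 29599. Measured against Ang II replicates 2 and 3, its shortest transcripts, in the lowest of 5 equal groups of genes with a median length of 919 bases, were higher by a median of 0.44 on the log2 scale, and its longest, at 4756 bases, had a median of -0.24.

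**Figure D3:**
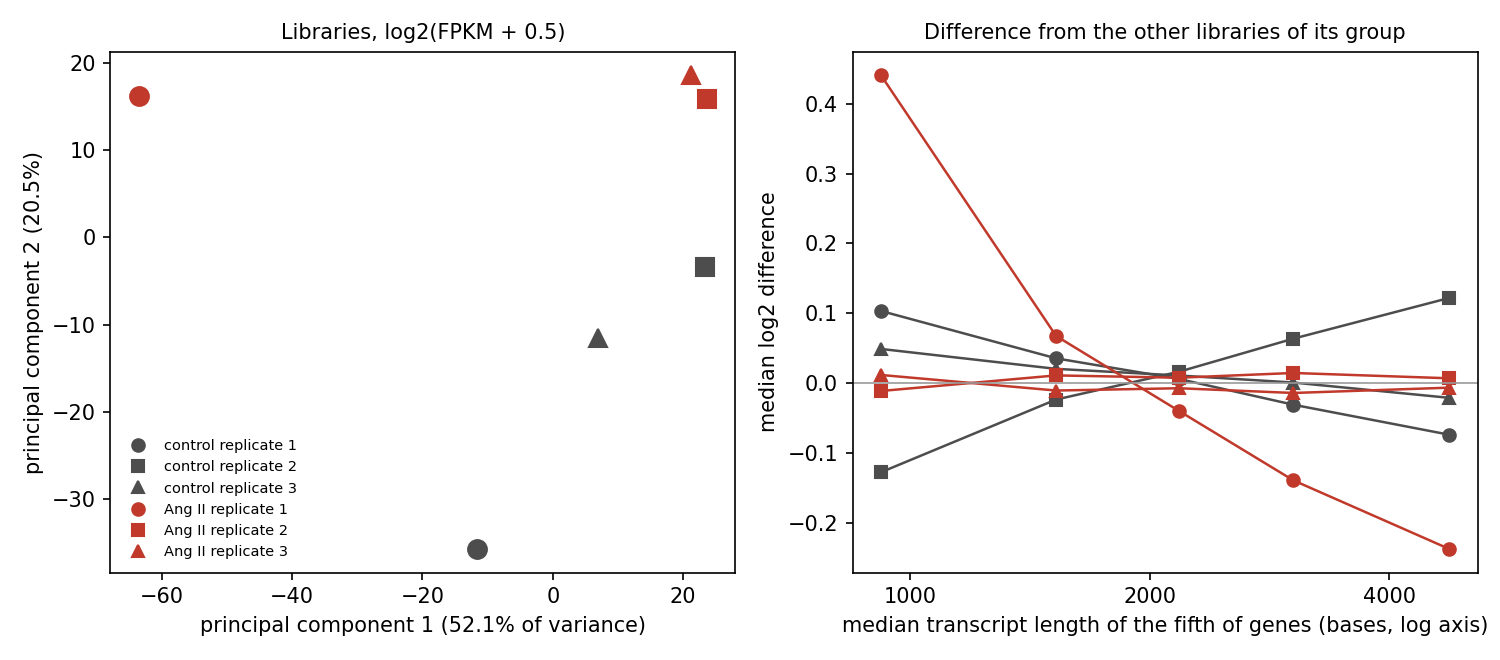
Left, the first 2 principal components of log2(FPKM + 0.5), 1 point per library; Ang II replicate 1 lies at -63.5 on the first. Right, the median log2 difference of each library from the others of its group (from replicates 2 and 3 for Ang II replicate 1, and from each other for those 2) in 5 equal groups of genes by transcript length (x axis, bases, log scale), running from 0.44 to -0.24 in Ang II replicate 1.

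Leaving out Ang II replicate 1 for a fuller list of genes was a choice made after the values were seen. Besides Hbegf (log2 change 3.09, SE 0.12) and Mt2 (2.88, SE 0.30), the largest rises by the rule for named genes were Nfix (3.15, SE 0.41), a transcription factor of the nuclear factor I family, Abra (2.81, SE 0.22), an actin-binding protein of striated muscle, Pdk4 (2.70, SE 0.15) and Pcdhgc3 (2.50, SE 0.20). Pcdhgc3 is a protocadherin whose exons overlap other genes of its cluster, so its counts are uncertain. Nfix stood at 47.9 CPM in Ang II replicate 2, 18.2 CPM in replicate 3 and 9.50 CPM in replicate 1, against 3.02 to 4.11 CPM in control hearts, so its place rests largely on replicate 2. Among the largest falls were Brox (-2.97, SE 0.16), Arpc5 (-1.44, SE 0.17), Arhgap18 (-1.32, SE 0.12), G0s2 (-1.23, SE 0.15), an inhibitor of triglyceride lipase, and the immediate early gene Ier2 (-1.16, SE 0.13). Adjusted p-values of these rises and falls ran from 0.00488 to 0.0472 by edgeR. Of the 129 genes, Ang II replicate 1 lay beyond all 3 controls on the side of replicates 2 and 3 in 93, on the other side in 30 and within their range in 6; the genes had been chosen with these controls. The 30 included Brox (24.9 CPM), Arpc5 (29.0 CPM), Pdk4 (64.8 CPM) and Pcdhgc3 (0.276 CPM), and Ier2 (25.3 CPM) lay within their range. Among 3914 gene ontology and pathway terms tested per direction, 1 was enriched, myofibril, with 6 of its 36 tested genes among the rises (Abra, Ankrd1, Ankrd23, Lmod2, Nrap and Twf2; Fisher's exact test, adjusted p = 0.000531). Among genes changed at least 2-fold it did not pass (adjusted p = 0.108), and 0 terms were enriched. With all 6 libraries 0 of 3845 terms were enriched in either direction, with 5 annotated genes called.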

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

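Robust edgeR, voom weights, leaving out mitochondrial genes with pseudogenes, the length correction, camera on log2 CPM and terms without Ang II replicate 1 were tests chosen after the data were seen. Against 6 genes by edgeR, counts were 12 with no filter, 276 by DESeq2, 348 by voom with library quality weights and 10 without mitochondrial genes and pseudogenes. They were 10 with the length correction and 10 for the same genes uncorrected. Each included the 6. Robust edgeR gave 4, all among the 6, and lost Xirp1 and P2rx5. limma with arrayWeights gave 5097, with a weight of 63.9 on control replicate 3 and of 0.0817 to 2.99 on the others. Limma gave 3 on FPKM (Mt2 and Gm27529 higher, Fam102b lower), 2 with a pseudocount of 0.1, 3 with 1, 1 with no filter, 3 at FPKM of at least 1, 3 rescaled, 3 without mitochondrial genes and 1 with the replicate number as a block. These had none of the 6. Limma with median-of-ratios factors gave 5 and with quantile normalization 5, each sharing 2 with the 6. The block left 0 by edgeR, with 1104 of 16759 genes tested at an unadjusted p under 0.05. The labels do not say whether hearts of equal number share more than that number. Libraries left out in turn gave 0 to 129 genes, and 9 to 14 lists. With an estimated correlation 0 lists passed, and by fry 0. Enriched terms numbered 0, and 1 without Ang II replicate 1. The PPARα list's adjusted p was 3.92e-05 with arrayWeights, 0.0132 on log2 CPM, 0.0443 with the length correction, 0.795 and Down with quantile normalization, and 8.97e-08 to 0.873 with libraries left out. The NF-κB target list stayed Down and past no threshold in all of its alternatives, from 0.0942 to 0.987.

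Of 1376 values of named genes under alternatives, 1175 kept direction and side of the threshold, 69 lost the call, 121 gained it and 11 changed sign, none past a threshold. The sign changes were log2 values of 0.20 for S100a9, 0.18 for Ppara, 0.10 for Nfkb1 and 0.065 for Myh7 with arrayWeights, and -0.075 for Ndufa9 with quantile normalization. Postn gave -0.018 with the block, -0.014 with median-of-ratios factors, and -0.069 to 0.65 with libraries left out, below 0 without Ang II replicates 2 (-0.069) and 3 (-0.021). Tnf gave -0.88 to 0.96, below 0 without Ang II replicate 1 (-0.88) and control replicate 3 (-0.16). Of 595 values of the other lists, 536 kept their side of the threshold, 46 lost the call and 13 gained it. Over all tested lists 35 values changed sign with neither value past the threshold, the PPARα list with quantile normalization among them. Quantile normalization ended the calls of cardiomyocyte genes (0.386), nuclear respiratory chain subunits (0.794), mitochondrially encoded genes (0.386), oxidative stress genes (0.273) and granulocyte markers (0.0635). The cause was not tested in any of these. Il6 had at most 14 counts in a library and was not tested; Tnf had at most 37 and Il1b 130.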

Other observations

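Tests of a wrong label, which replaced 3 earlier forms of it (the last left the question open), of length and GC content, which replaced bounds on rho that ignored the size of a trend, of less blood, of a control rich in blood and of the time of day were chosen only after related results were seen; those of shared list members and other splits were written before.

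Clock genes did not pass camera (adjusted p = 0.0968), with 0 of 19 called over all genes by edgeR, 2 higher and 3 lower at an unadjusted p under 0.05, 4 by DESeq2, and 1 higher and 3 lower adjusted over the list alone. The members, chosen after their values were seen, were Nfil3 (log2 change 1.41), Nr1d1 (-0.78), Ciart (-1.54) and Bhlhe40 (-0.97). Atrial genes had 8 of 9 folds above 0 (median 0.80; camera adjusted p = 0.122), with 0 called over all genes by edgeR, 3 higher and 1 lower unadjusted, 2 by DESeq2, and 2 higher adjusted over the list alone, Nppa and the atrial myosin light chain Myl4 (1.56). Camera covered 6 members of this list, and with an estimated correlation its adjusted p = 0.633. It passed without control replicate 1 (0.0328), with no filter (0.00123), on log2 CPM (0.00209) and with values rescaled to a common sum (0.0483). Adipocyte markers had a median of -2.31 in Ang II replicate 1 and of -0.29 and -0.36 in replicates 2 and 3 (camera adjusted p = 0.341), and passed, lower, with no filter (0.00325). Macrophage markers (0.327 with all libraries) passed lower without Ang II replicate 1 (5.16e-05; adjusted p = 0.775 with an estimated correlation), with a median of 0.15 in that library and -0.37 and -0.20 in replicates 2 and 3. Citrate cycle and branched-chain amino acid genes (0.379) passed higher without it (6.30e-05; adjusted p = 0.825 with an estimated correlation) and with arrayWeights (0.00198). Medians without Ang II replicate 1 were -0.30 and 0.29 for these 2 lists.

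The other lists did not pass camera with the settings of the report. Adjusted p-values were 0.654 for fibroblast markers (Down, though fry gave Up), 0.176 for conduction genes, 0.466 for glycolysis, 0.136 for the unfolded protein response, 0.654 for cell death and 0.581 for skeletal muscle markers. The unfolded protein response list passed, lower, with quantile normalization (0.0108) and with the length correction (0.0443). In others the median, mean and test differed in sign: mural cells (median -0.10, mean 0.09, test Up, 0.814), renin-angiotensin genes (-0.09, 0.00, Down, 0.523), proliferation genes (0.14, 0.09, Down, 0.408), sex-linked transcripts (0.04, 0.26, Down, 0.673) and mesothelial and neural markers (-0.55, -0.47, Up, 0.643). Camera covered 5 proliferation genes and 3 mesothelial and neural markers, against 29 and 9 in the medians. It covered 10 renin-angiotensin genes against 15, 4 sex-linked transcripts against 5, and 17 mural cell markers against 17. Cenpf, chosen after its values were seen, was the proliferation gene that passed adjusted over the list alone (log2 change -1.81). Lymphocyte markers had 0 of 14 members called by edgeR or DESeq2 and 0 at an unadjusted p under 0.05.

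Ang II replicate 1 stood apart from the other 5 libraries, and its deviation from replicates 2 and 3 gave Spearman's rho across genes of -0.260 with transcript length and 0.158 with GC content (0.218 and -0.140 in controls, with smaller trends; genes are not independent replicates). Removing the trend took its mean r from 0.932 to 0.935 for length and 0.933 for GC content, against at least 0.964 in the other libraries, which argues against either as the whole cause; they held shares of 0.130 and 0.0195 of the variance of its deviation from the mean of all libraries. A wrong label alone would leave it among the controls, but its r with a control was at most 0.937, against 0.970 to 0.974 between controls. Its r with Ang II replicates 2 and 3 was 0.918 and 0.925. It thus lay apart from both groups, and r does not give its label. The hypertrophy list argues against a control heart. Once the length trend was removed, its median was 0.93 here, 0.93 and 0.80 in replicates 2 and 3, and -0.17 to 0.13 in controls. Yet of the 14 lists that passed without this library 5 then lay beyond the controls on the Ang II side, 4 on the other and 5 within their range. Before the length trend was removed these counts were 8, 5 and 1. Of genes chosen without this library and 1 control, it lay on the Ang II side in 95 of 128, 89 of 123 and 98 of 129. The held-out control did so in 68, 91 and 60. A weaker response to Ang II alone would place this library between the controls and replicates 2 and 3. Its r with controls was 0.917 to 0.937, below the 0.963 to 0.970 of replicates 2 and 3 with controls. That argues against a weaker response as the whole cause. RNA quality and a weaker response in part stay open, as untested.

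Red blood cell transcripts were lower in Ang II hearts, by a median of -1.83 on the log2 scale. One control rich in blood would not leave -1.49 without control replicate 1 (interquartile range 0.970), with every control's median above every Ang II heart's. Less blood left in the Ang II tissue could also lower white cell markers, whose median was -0.094 over 24 lymphocyte and granulocyte genes with an interquartile range of 1.28, 11 above 0 and 13 below. These values are too spread to decide, so tissue blood and a change in red cells cannot be told apart.

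Glucocorticoid-induced genes were higher in Ang II replicates 2 and 3. The 7 genes in no other list gave a camera adjusted p of 0.744 with all 6 libraries, so the list's call there needed its shared members. Without Ang II replicate 1 these 7 gave 0.0222 by camera (adjusted p = 0.775 with an estimated correlation). By the preset correlation alone, members of other lists thus did not carry all of the rise in replicates 2 and 3. Another time of collection may move clock genes as well, and 9 of these had a median log2 change of -0.31 without Ang II replicate 1 (interquartile range 0.768, 3 above 0 and 6 below). That decides nothing, so a different hour, stress at collection and Ang II itself cannot be told apart.

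Of 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real 6, the real split itself, and the highest other gave 1. For lists, 1 gave as many as the real 12, and the highest other gave 10. At an unadjusted p under 0.05 the real split gave 1258 genes by edgeR and did not come first. Control replicates 1 and 3 with Ang II replicate 1, against the rest, gave 1462. The remaining splits gave 250 to 559. These 10 splits are too few for a share under 0.05.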
